A study of Mus musculus with 12 samples.

How the data were processed

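RNA of murine splenic B cells was profiled in 12 libraries, 3 for each of 4 groups. Per the labels, the cells came from BALB/c mice of post-natal day 42 to 49 and were kept for 24 h in RPMI medium with fetal bovine serum, with 1 µM of a CpG ODN in the treated groups, total RNA was extracted with a column kit, and libraries followed DNBSEQ protocols. The group of each library was taken from its treatment label and its number from its title. How the B cells were purified from the spleen is not given in the sources used here.

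The deposited table gives FPKM (fragments per kilobase of transcript and M mapped fragments, with M for mega) for each library, computed by the authors and rounded to 2 decimals, per the file headers. The submitters' processing notes name HISAT, StringTie, Bowtie2 2.2.5, RSEM 1.2.8, GATK and the mouse build mm10, without a role or order. The deposited table also holds the authors' log2 ratios between groups and their p-value and q-value for each of the 6 comparisons, and the tool behind them is not given in the sources used here. Gene positions and lengths are other columns of the deposited table, counted from 1, and coordinates are printed as it gives them. Of its 28021 entries, 2 named no gene and were left out. The remaining 28019 were 19682 known genes and 8337 unnamed loci, which the deposited table lists apart from known genes. A spreadsheet had turned 26 symbols into dates, and these were restored through the gene identifier from a RefSeq table of assembly GRCm38.p6, in which 19635 of the known genes were found, 95.9% of them under the same symbol. Only names were used from that table. GC content was computed from the longest GENCODE transcript of each gene symbol.

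FPKM are not counts, so no count model was fitted. The design written before the data were examined set a count test for counts and, for a table of normalized values only, limma's trend method on log2(FPKM + 1), which was used. Genes above 1 FPKM in at least 3 libraries were tested, 15853 in all (10860 known genes and 4993 unnamed loci). All 12 libraries entered a single fit with 4 group means, so that the 6 comparisons share 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene counts as changed at an adjusted p under 0.05. A log2 change is on the log2(FPKM + 1) scale and understates the change of low genes. R 4.3.3, limma 3.58.1, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.

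Fixed lists of genes, 25 in number, were tested with limma's camera, which asks whether members moved together against all other genes, with a preset correlation of 0.01 between genes and again with the correlation estimated from the data. The lists were type I interferon response, interferon-gamma-inducible GTPases and regulators, cytokines and chemokines, NF-kappaB targets, activation and costimulation markers, antigen presentation, G1/S and DNA replication, G2/M and mitosis, MYC and ribosome biogenesis, glycolysis, plasma cell and secretory programme, B cell identity, quiescence and homing, class switching and germinal centre, Toll-like receptors and signalling, feedback inhibitors, anti-apoptotic, pro-apoptotic, marginal zone and B-1 markers, and markers of T cells, monocytes and macrophages, NK cells, dendritic cells, neutrophils, and erythroid cells and platelets. Of the 399 list genes 395 were in the table. The NK cell and neutrophil lists had too few measured genes, so 23 lists were tested in 6 comparisons and the 138 p-values were adjusted together. Of 74 calls with the preset correlation, 0 held with an estimated correlation, at which p-values under 0.05 before adjustment remained for some lists.

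Genes are named by a fixed rule. It takes, per comparison, the 6 highest and 6 lowest log2 changes among changed genes with at least 10 FPKM in the higher group and no overlap between the libraries, then the 3 largest changes of each list and the largest the other way, and 12 genes fixed whatever their result, some of which are not reported here. Where the lowest were unnamed loci, the 6 lowest genes with a symbol were used, a choice made after their values were seen. A gene called against the control may also be given in the other comparisons. Levels are means ± SD over 3 libraries, and log2 changes carry ± SE.

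Depth was estimated from the table, since low FPKM of genes with 1 transcript lie on steps that correspond to whole fragments. Taking effective lengths as the transcript length less 100 bases, 72.5% to 89.5% of low values fell within 0.2 of a whole fragment, against 40% by chance, so the depths are estimates and no counts were recovered for testing. They ranged from 14.3 to 25.6 M fragments. The 95% interval of a log2 change had a median half-width of 0.288.

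Whether replicate numbers pair libraries across groups was checked by correlating each library's deviations from its group mean across genes, which are not independent replicates. CpG-B and CpG-C libraries of the same number had correlations of 0.59, 0.54 and 0.74. CpG-B library 2 with CpG-C library 1 had 0.551, and CpG-B library 1 with CpG-C library 2 had 0.509. The check thus shows that the third libraries deviate together, and cannot tell whether libraries 1 and 2 are paired by number. The labels state no pairing. The results given for CpG-C against CpG-B, with their SE, intervals and list tests, come from the fit without pairs set beforehand, and the fits with pairs are given beside them. For CpG-A and control they were 0.47, -0.12 and 0.52, and for the other comparisons they lay between -0.13 and 0.05, so these are not treated as paired.

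The fit and the list test were tested on simulated data of 15853 genes, with 67 genes changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. A change of 1 on the log2 scale was recovered in 92.5%, 89.6% and 98.5% of genes for CpG-A, CpG-B and CpG-C against control, 92.5% for CpG-B against CpG-A, 89.6% for CpG-C against CpG-A and 91% for CpG-C against CpG-B. A change of 0.5 was recovered in 43.3%, 37.3% and 34.3% for the classes against control, in 28.4% for CpG-B and for CpG-C against CpG-A, and in 38.8% for CpG-C against CpG-B. Between 4 and 10 unchanged genes were called per comparison, and a shifted list was called in 6 of 6 comparisons, with the preset and with an estimated correlation. Simulated genes were drawn independently, so these figures do not cover data in which genes move together and cannot back the calls with the preset correlation. Alternatives covered the pseudocount, filters on low values, scaling, the libraries in the fit, the replicate number as a block and leaving out each library in turn. The planned count-based alternatives were not run, because the table holds no counts.

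The authors' deposited table was compared with the fit. Its q-values were under 0.05 for 24545, 25566 and 25571 genes in CpG-A, CpG-B and CpG-C against control and for 6526 in CpG-C against CpG-B. In the authors' deposited table the q-value was smaller than the p-value for 89.7% of genes in CpG-A against control. Of the 10426 genes called here in that comparison, 10400 had the same direction in the authors' deposited table, as did 29 of 29 in CpG-C against CpG-B.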

Results

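The RNA of murine splenic B cells was compared after 24 h of culture with or without 1 µM of a CpG oligodeoxynucleotide (ODN) of class A, B or C. CpG ODNs are short synthetic DNAs with unmethylated CpG motifs, the ligand of the endosomal Toll-like receptor TLR9. Class A ODNs carry a palindromic phosphodiester CpG core with phosphorothioate poly-G ends, class B ODNs are linear and fully phosphorothioate, and class C ODNs are fully phosphorothioate with a palindrome. The labels give the class of each ODN but no sequence. The series set out to characterise the classes in B cells, and each group, the control included, held 3 libraries. The labels do not say whether these came from separate cultures or animals, so p-values measure only the spread between the libraries, which may be technical.

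Steps between low FPKM values placed the depth at 14.3 to 17.2 M fragments (M, mega) in the control libraries, 21.2 to 22.4 with CpG-A, 24.3 to 25 with CpG-B and 24.6 to 25.6 with CpG-C. At these depths 1 fragment on 1 kilobase corresponded to between 0.039 and 0.07 FPKM. The control libraries listed 15491 to 18591 genes at 1 FPKM or more, against 11089 to 11562 with CpG-A and 10761 to 11070 with CpG-B or CpG-C. Low signal was higher in the controls as well, at unnamed loci and at olfactory and vomeronasal receptor genes. The 8337 unnamed loci, which the deposited table lists apart from known genes, had a median of 1.73 FPKM in the controls, 0.343 with CpG-A, 0.0667 with CpG-B and 0.05 with CpG-C. The 1293 olfactory and vomeronasal receptor genes, which are used by sensory neurons, had a mean of 0.216 ± 0.0547 FPKM in the controls, 0.0502 ± 0.014 with CpG-A, 0.0135 ± 0.00084 with CpG-B and 0.0116 ± 0.00272 with CpG-C (SD, n = 3). Falls of genes that stood at about 1 to 3 FPKM in the controls lie at the level of the unnamed loci, above the mean of the receptor genes. In a principal component analysis PC1 held 83.3% of the variance and ran from the controls through CpG-A to CpG-B and CpG-C. The analysis took in all 15853 genes tested, 4993 of them unnamed loci, and was not made for known genes alone. How far the low signal of the controls enters PC1 was not tested. On PC3, with 3.4%, the third CpG-B and CpG-C libraries stood apart, at 26.2 and 22.3 against -12.3 to -9.90 for the other libraries of these classes.

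**Figure D1:**
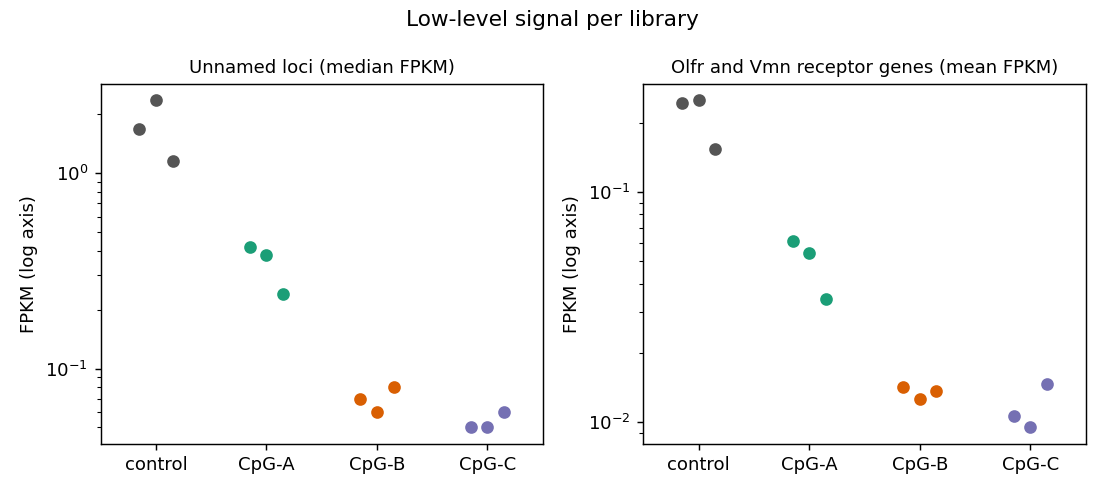
Each point is 1 library, and the log axes show the median FPKM of the 8337 unnamed loci and the mean FPKM of 1293 olfactory and vomeronasal receptor genes. Control libraries had the highest values, with a group mean of 0.216 FPKM for the receptor genes against 0.0502 with CpG-A and 0.0116 with CpG-C.

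CpG-A raised interferon-response, cell-division and MYC-linked genes in B cells, with the chemokines Ccl3 and Ccl4, and lowered genes of quiescence and homing. Of the 28 measured members of the type I interferon list, 27 rose and 1 did not pass, with a median log2 change of 1.87, or 2.03 above the median of all genes. Irf7, the transcription factor that amplifies interferon production, rose from 4.06 ± 0.373 to 70.7 ± 32.6 FPKM (SD, n = 3), a log2 change of 3.72 ± 0.28 (adjusted p = 1.68e-06). Isg15, an interferon-induced ubiquitin-like protein, rose from 3.12 ± 0.426 to 24.3 ± 8.17 FPKM, and Ifit3, an interferon-induced antiviral protein, from 0.67 ± 0.26 to 18.8 ± 9.37 FPKM. Ly6a, which encodes the surface antigen Sca-1, had the highest log2 change of the genes the rule admits, 6.68 ± 0.32, from 1.07 ± 0.277 to 226 ± 95.6 FPKM, though reads of the Ly6 family can be shared between its members. The first CpG-A library stood below the other 2 in such genes. In CpG-A libraries 1, 2 and 3 Irf7 was at 38.2, 103 and 70.5 FPKM, Ifit3 at 8.33, 26.4 and 21.6 FPKM and Ly6a at 121, 307 and 250 FPKM, which also enters the comparisons of the classes. Of 10 interferon-gamma-inducible GTPases and regulators 8 rose, such as Irgm1, a GTPase of cell-autonomous defence (log2 1.10 ± 0.15). Camera called the interferon list at adjusted p = 8.33e-13, or adjusted p = 0.281 with an estimated correlation, and the GTPase list at adjusted p = 0.000678, or adjusted p = 0.281 with an estimated correlation. The deposited table places Irf7 (gene 54123) on chromosome 7 from 141263183 to 141266424 and Isg15 (gene 100038882) on chromosome 4 from 156199424 to 156200818, both on mm10.

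All 20 measured G2/M and mitosis genes and 20 of 22 G1/S and DNA replication genes rose with CpG-A, with median log2 changes of 2.45 and 1.59. Mki67, the proliferation antigen (gene 17345, chromosome 7, 135689788 to 135716379), rose from 4.68 ± 0.332 to 38.6 ± 3.67 FPKM, and Rrm2, a subunit of ribonucleotide reductase, from 5.38 ± 0.833 to 66.6 ± 2.79 FPKM. All 17 MYC and ribosome biogenesis genes rose, at a median log2 change of 1.17. Myc, the growth-promoting transcription factor (gene 17869, chromosome 15, 61985341 to 61990361), rose from 15.2 ± 1.82 to 60 ± 2.01 FPKM, and Npm1, a nucleolar protein of ribosome assembly, by 1.53 ± 0.18 on the log2 scale. Of 16 glycolysis genes 12 rose, among them Ldha, lactate dehydrogenase A (log2 1.77 ± 0.10). The lists were called at adjusted p = 4.29e-17 (G2/M), 5.59e-11 (G1/S), 4.16e-08 (MYC) and 1.56e-07 (glycolysis), and with an estimated correlation at adjusted p = 0.116, 0.286, 0.313 and 0.127.

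Of 13 measured cytokine and chemokine genes 8 rose and 3 fell with CpG-A. Ccl3 and Ccl4, chemokines that attract T cells and monocytes, rose from 4.54 ± 1.21 to 74.3 ± 3.07 FPKM and from 2.62 ± 0.693 to 44.7 ± 5.76 FPKM, and Tnf from 4.80 ± 0.304 to 19.2 ± 0.646 FPKM. Ccl22, a chemokine for CCR4, fell from 35.6 ± 4.05 to 19.1 ± 1.42 FPKM. Il10, an immunosuppressive cytokine, rose by 1.60 ± 0.16 and Il6 by 1.21 ± 0.12 on the log2 scale, and Prdm1, which encodes the plasma cell regulator Blimp-1, by 0.94 ± 0.11. NF-kappaB targets rose in 9 and fell in 2 of 17 cases, activation and costimulation markers in 6 and 1 of 16, class-switching and germinal centre genes in 7 and 1 of 11, and plasma cell and secretory genes in 13 and 1 of 16. Batf, a transcription factor needed for class switching, rose from 12.3 ± 1.34 to 59.9 ± 4.23 FPKM, while Cd69, an early activation antigen, fell from 27.3 ± 1.79 to 17.9 ± 1.12 FPKM and Sdc1, the plasma cell antigen CD138, from 23.1 ± 0.557 to 10.2 ± 0.762 FPKM. Cd86, a costimulatory ligand, did not pass (log2 0.07 ± 0.12, adjusted p = 0.635). Anti-apoptotic genes rose in 5 and fell in 1 of 9 cases, pro-apoptotic genes rose in 6 of 12, and marginal zone and B-1 markers rose in 7 and fell in 1 of 10 (4 and 1 with upper-quartile and 3 and 1 with TPM scaling). Camera called these 8 lists at adjusted p = 0.00655 (cytokines), 0.00103 (NF-kappaB), 0.0219 (activation), 0.00247 (class switching), 5.11e-07 (plasma cell), 0.0179 (anti-apoptotic), 0.00355 (pro-apoptotic) and 0.00791 (marginal zone). With an estimated correlation the same lists had adjusted p = 0.11, 0.154, 0.25, 0.11, 0.266, 0.228, 0.101 and 0.255.

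Quiescence and homing genes fell in 12 and rose in 1 of 16 cases with CpG-A (adjusted p = 0.0355, or adjusted p = 0.653 with an estimated correlation). Cxcr4, the receptor for CXCL12, fell from 483 ± 60 to 119.8 ± 11.7 FPKM, and S1pr1, the sphingosine-1-phosphate receptor of lymphocyte egress, from 257 ± 13.9 to 87.0 ± 3.5 FPKM. Of 21 B cell identity genes 13 fell and 3 rose, of 18 antigen presentation genes 9 fell and 5 rose, of 18 Toll-like receptor and signalling genes 6 fell and 2 rose, and of 14 feedback inhibitors 5 rose and 2 fell. Camera called none of these lists (adjusted p = 0.58, 0.605, 0.483 and 0.13). Fosb, an AP-1 subunit and the lowest change among genes with a symbol that the rule admits, fell by 3.03 ± 0.17 on the log2 scale. Tlr7, an RNA sensor, rose by 1.95 ± 0.19, whereas Tlr9, the CpG receptor itself, had 44.2 ± 6.86 FPKM in the controls and 65.6 ± 6.61 with CpG-A and did not pass (adjusted p = 0.0801). Adjusted over the list alone, the counts of all these lists were the same, except 2 higher and 3 lower for the Toll-like receptor list.

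Of 15853 genes tested, 3747 rose and 6679 fell with CpG-A, 750 and 3574 of them at least 2-fold. Among known genes 3561 rose and 2395 fell, and among unnamed loci 186 rose and 4284 fell, at a median log2 change of -1.08. With the filter at 5 FPKM 3260 rose and 1931 fell, so the excess of falls rests on low values. Of 474 changes of named genes over the 6 comparisons, for which the rule itself favours separation, the libraries of the 2 groups overlapped in Irf7 and Gnl3 in CpG-C against CpG-A.

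With CpG-B the cells again raised interferon, cell-division and glycolysis genes, along with Il10 and Prdm1. Il10 (gene 16153, chromosome 1, 131019845 to 131024970) rose from 0.81 ± 0.272 to 30.8 ± 5 FPKM (log2 4.13 ± 0.16, adjusted p = 1.73e-09), and Prdm1 from 2.11 ± 0.303 to 19.0 ± 0.66 FPKM. All 16 glycolysis genes rose, at a median log2 change of 2.16. Slc16a3, a lactate exporter (gene 80879, chromosome 11, 120948484 to 120959000), rose from 0.163 ± 0.0416 to 39.9 ± 7.69 FPKM and Pgk1, phosphoglycerate kinase, from 86.1 ± 2.26 to 933 ± 27.4 FPKM. Camera called glycolysis at adjusted p = 9.63e-12, or adjusted p = 0.0722 with an estimated correlation.

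The interferon list again rose in 27 of 28 members, at a median log2 change of 2.52, and interferon-gamma-inducible genes rose in 8 and fell in 1 of 10 cases. Isg15 reached 38.6 ± 12 FPKM, Irf7 47.2 ± 5.97 FPKM and Oas1a, a sensor of double-stranded RNA, 25 ± 8 FPKM from 0.73 ± 0.125. All 20 G2/M genes and 21 of 22 G1/S genes rose, with median log2 changes of 3.09 and 1.62. Mki67 reached 51.7 ± 4.40 FPKM and Ccnb2, cyclin B2, 59.2 ± 7.16 FPKM from 4.44 ± 0.301. MYC and ribosome biogenesis genes rose in 7 of 17 cases, Myc itself to 39.9 ± 15.6 FPKM. That count depended on the scaling, with 10 higher with median-of-ratios, 8 with upper-quartile, and 3 higher and 2 lower with TPM scaling. The third CpG-B and CpG-C libraries lay above the others of their group in 21 of 22 G1/S genes and 17 of 17 MYC genes, with median log2 differences of 0.722 and 0.704 for G1/S and 0.433 and 0.809 for MYC. Camera called the interferon, GTPase, G2/M, G1/S and MYC lists at adjusted p = 5.12e-13, 0.000194, 3.93e-16, 4.88e-10 and 0.00642, and with an estimated correlation they had adjusted p = 0.281, 0.255, 0.119, 0.286 and 0.653.

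Feedback inhibitors rose in 9 and fell in 3 of 14 cases with CpG-B. Atf3, a stress-induced repressor of Toll-like receptor responses, rose from 0.293 ± 0.0929 to 42.5 ± 8.47 FPKM, and Socs3, a suppressor of cytokine signalling, from 1.27 ± 0.0839 to 42.8 ± 19.4 FPKM. Class-switching genes rose in 9 and fell in 1 of 11 cases, plasma cell genes in 14 and 1 of 16, NF-kappaB targets in 9 and 5 of 17 (8 and 8 with TPM scaling), and activation markers in 9 and 3 of 16. Il2ra, the interleukin-2 receptor alpha chain, rose by 2.45 ± 0.12 on the log2 scale and Cd69 by 1.11 ± 0.11, whereas Icosl, the ligand of ICOS, fell by 2.59 ± 0.24, Cd86 fell by 0.61 ± 0.12 and Sdc1 fell by 3.33 ± 0.17. Anti-apoptotic genes rose in 5 and fell in 1 of 9 cases (8 and 0 with median-of-ratios and 4 and 3 with TPM scaling). Pro-apoptotic genes rose in 9 of 12 (11, or 7 with 1 lower, under these scalings). Marginal zone and B-1 markers rose in 6 and fell in 2 of 10. Camera called these lists at adjusted p = 0.00169 (feedback), 0.000106 (class switching), 1.14e-07 (plasma cell), 0.00767 (NF-kappaB), 0.00424 (activation), 0.00781 (anti-apoptotic), 0.000106 (pro-apoptotic) and 0.0181 (marginal zone). With an estimated correlation they had adjusted p = 0.237, 0.0604, 0.255, 0.229, 0.17, 0.176, 0.0604 and 0.281. Of 13 cytokine genes 7 rose and 4 fell, and the list was not called (adjusted p = 0.0764).

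Quiescence and homing genes fell in 12 and rose in 1 of 16 cases (adjusted p = 0.043, or adjusted p = 0.654 with an estimated correlation), with S1pr1 at 25.8 ± 5.41 and Cxcr4 at 52.9 ± 4.41 FPKM. The third CpG-B and CpG-C libraries lay below the others of their group in 13 of 16 quiescence genes and 16 of 21 B cell identity genes, and above them in 17 of 20 G2/M genes. B cell identity genes fell in 12 and rose in 4 of 21 cases and antigen presentation genes fell in 10 and rose in 5 of 18, and camera called neither list (adjusted p = 0.926 and 0.944). Fcer2a, the low-affinity IgE receptor CD23, fell from 325 ± 40.3 to 44.2 ± 2.88 FPKM, while Pou2af1, a B cell coactivator, rose from 167 ± 12.7 to 506 ± 23.9 FPKM. H2-Ob, a chain of the class II peptide-loading inhibitor H2-O, fell by 2.22 ± 0.28, while Psmb9, an immunoproteasome subunit, rose by 2.01 ± 0.15 on the log2 scale. Toll-like receptor and signalling genes rose in 5 and fell in 9 of 18 cases, which turned to 8 and 7 with median-of-ratios scaling (adjusted p = 0.528), and Tlr9 did not pass at 30.2 ± 11.6 FPKM (adjusted p = 0.0556). Apoe, apolipoprotein E (gene 11816, chromosome 7, 19696244 to 19699188), fell from 1431 ± 122 to 43.1 ± 15.9 FPKM and Ccl22 (gene 20299, chromosome 8, 94745684 to 94751388), from 35.6 ± 4.05 to 0.143 ± 0.0404 FPKM. Adjusted over the list alone, the counts were the same for every list in CpG-B against control.

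With CpG-B 4075 genes rose and 8219 fell, 1373 and 5207 of them at least 2-fold. Known genes were split 3783 to 3836, and unnamed loci 292 to 4383 at a median log2 change of -1.43. Changes of at least 2-fold turned to 1153 rises and 958 falls with the filter at 5 FPKM, and to 1207 and 1056 in a fit of known genes only. Of all changes 33.1% were rises, and 44%, 33.1% and 21.8% with median-of-ratios, upper-quartile and TPM scaling, under which the median log2 change of all genes went from -0.315 to -0.104, -0.32 and -0.614.

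CpG-C changed largely the lists that CpG-B changed. Il10 rose to 22 ± 3.01 FPKM, Prdm1 to 17.0 ± 2.45 FPKM, Slc16a3 to 44.6 ± 16.8 FPKM and Pgk1 to 956 ± 139 FPKM (log2 3.45 ± 0.09, adjusted p = 2.03e-10). Scd2, a stearoyl-CoA desaturase of fatty acid synthesis (gene 20250, chromosome 19, 44293676 to 44306864), rose from 2.45 ± 0.381 FPKM in the controls to 263 ± 69.1 with CpG-C and 243 ± 69.2 with CpG-B. The interferon list rose in 27 of 28 members (median log2 change 2.01), GTPases in 8 of 10 with 1 fall, G2/M in 20 of 20 (3.24), G1/S in 20 of 22 (1.80), MYC in 10 of 17 (0.62; 15 with median-of-ratios and 9 with TPM scaling) and glycolysis in 16 of 16 (2.40). Camera called them at adjusted p = 2.57e-11, 0.00092, 2.72e-16, 2.76e-10, 0.000421 and 3.16e-12, and with an estimated correlation they had adjusted p = 0.286, 0.286, 0.119, 0.286, 0.55 and 0.0706. Isg15 stood at 15.9, 18.4 and 55.1 FPKM in the 3 CpG-C libraries, so its mean of 29.8 ± 21.9 FPKM rests largely on the third.

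Plasma cell genes rose in 14 and fell in 1 of 16 cases with CpG-C, class-switching genes in 9 and 1 of 11, NF-kappaB targets in 9 and 4 of 17 (9 and 8 with TPM scaling), activation markers in 8 and 3 of 16, and feedback inhibitors in 8 and 3 of 14. Anti-apoptotic genes rose in 5 of 9 and pro-apoptotic genes in 8 of 12. With median-of-ratios scaling anti-apoptotic genes rose in 7 and pro-apoptotic genes in 11 cases, and with TPM scaling in 5 with 3 falls and in 7. The third CpG-B and CpG-C libraries also differed in plasma cell genes, where Jchain, the joining chain of secreted IgM and IgA, stood at 118 and 113 FPKM against 24.8 to 32.3 FPKM in the others. These lists were called at adjusted p = 2.33e-07, 7.5e-05, 0.0048, 0.00816, 0.00141, 0.0115 and 0.000194, and with an estimated correlation they had adjusted p = 0.255, 0.0604, 0.213, 0.2, 0.229, 0.2 and 0.0604. Quiescence genes fell in 12 of 16 cases (adjusted p = 0.0247, or adjusted p = 0.627 with an estimated correlation), led by S1pr1, which fell by 3.54 ± 0.17 on the log2 scale. Not called were cytokines (8 rose and 4 fell of 13, adjusted p = 0.0626), marginal zone markers (6 and 4 of 10, 0.0681), B cell identity (4 and 12 of 21, 0.752), antigen presentation (4 and 11 of 18, 0.768) and Toll-like receptors (5 and 8 of 18, 0.533). Fcer2a fell to 39.4 ± 12.3 FPKM and Cd86 to 4.13 ± 0.52 FPKM, whereas Tlr9 did not pass (log2 -0.31 ± 0.27, adjusted p = 0.306). Adjusted over the list alone, counts changed for antigen presentation (5 higher, 11 lower) and pro-apoptotic genes (7 higher).

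With CpG-C 4142 genes rose and 8126 fell, split 3877 to 3749 among known genes and 265 to 4377 among unnamed loci. At least 2-fold, 1332 rose and 5209 fell, which turned to 1128 and 947 with the filter at 5 FPKM and to 1165 and 1056 in a fit of known genes only. Rises were 33.8% of all changes, and 44%, 32.9% and 23.5% with median-of-ratios, upper-quartile and TPM scaling.

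**Figure D2:**
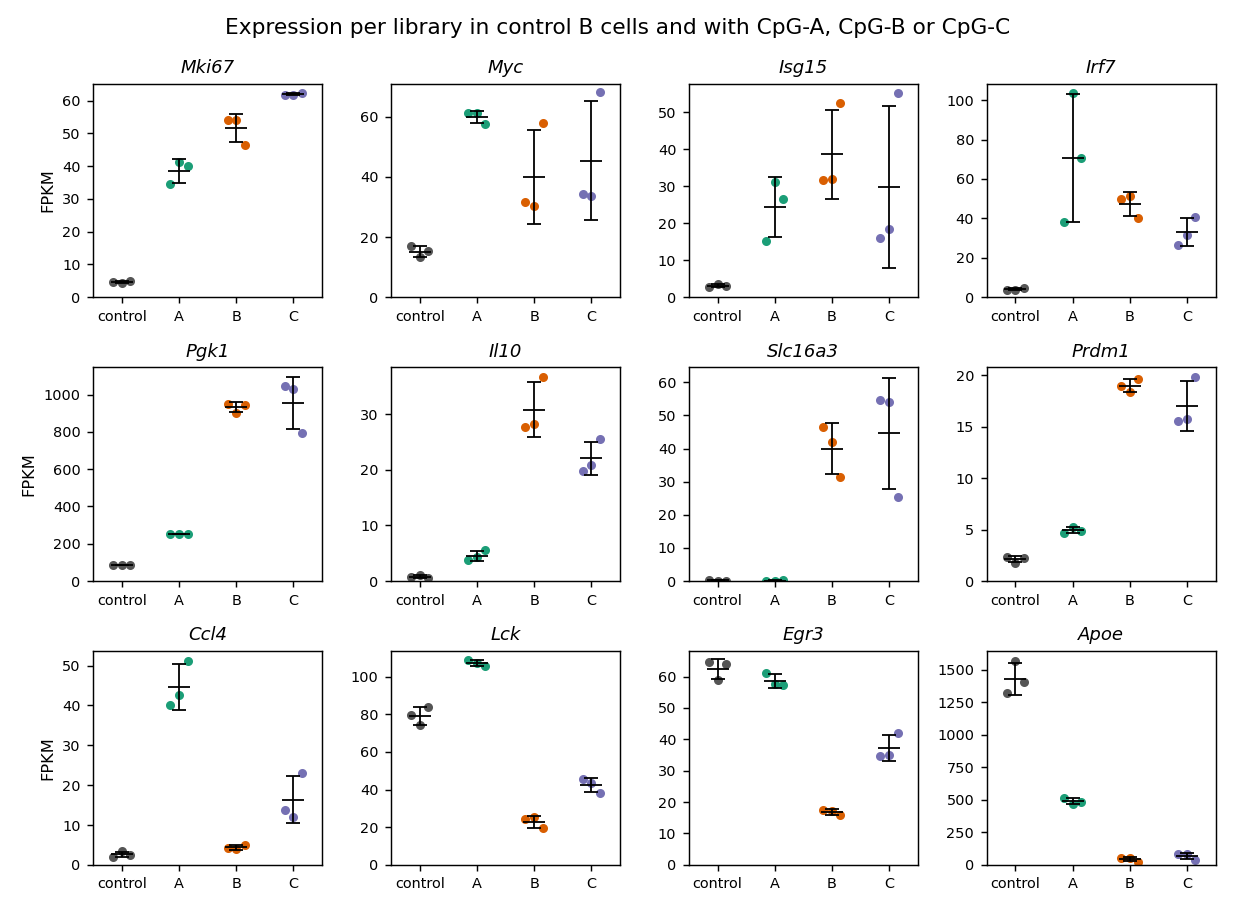
FPKM of 12 genes in each of the 12 libraries (points) with the mean and SD of the 3 libraries of a group. Il10 stood at a mean of 4.51 FPKM with CpG-A and 30.8 with CpG-B, and Ccl4 at 44.7 and 4.42.

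**Figure D3:**
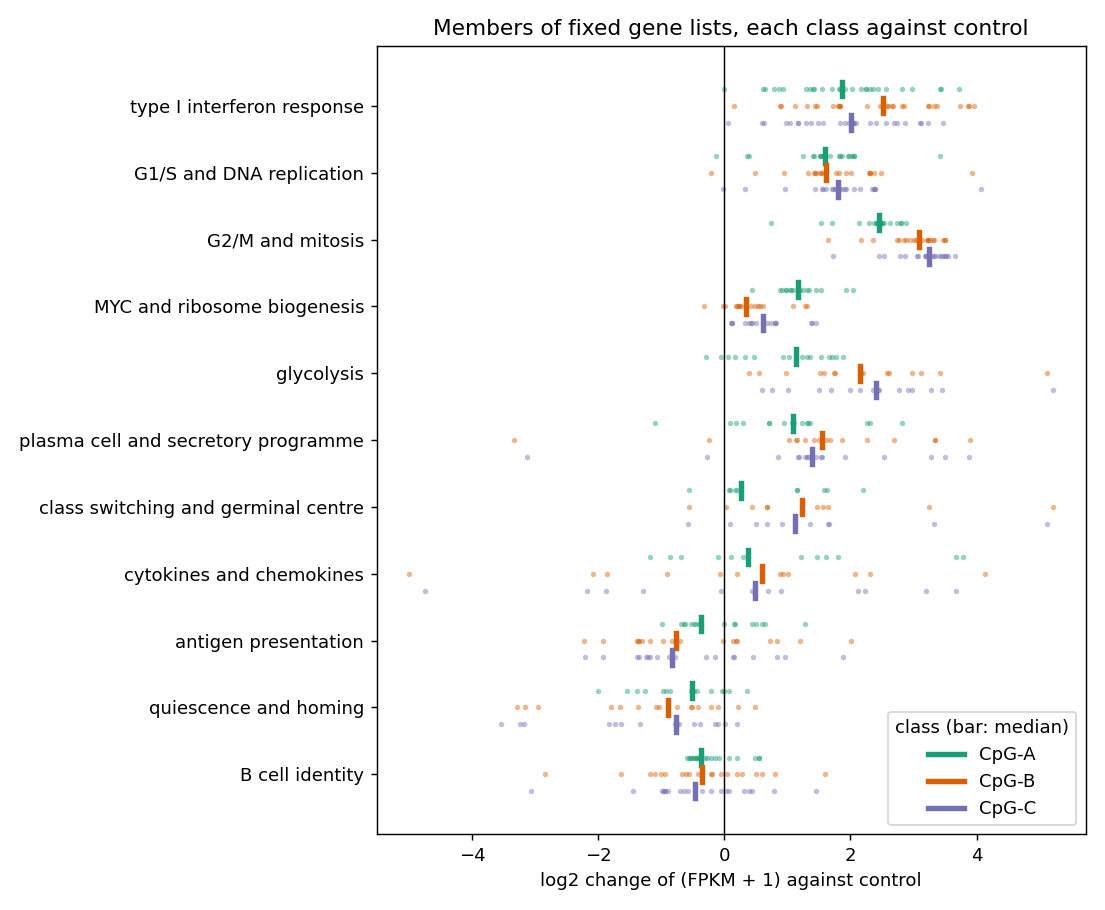
Log2 change against control, on the log2(FPKM + 1) scale, of each measured member of 11 gene lists (points) with the list median (bar), for each ODN class. Glycolysis medians were 1.13 with CpG-A, 2.16 with CpG-B and 2.40 with CpG-C, and MYC medians 1.17, 0.34 and 0.62.

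The ODN classes were then set against each other at the same dose and time. Compared with CpG-A, CpG-B gave higher glycolysis, mitosis, plasma cell and feedback genes and lower MYC-linked genes, with lower Ccl4 and Ccl22. Slc16a3 was at 0.123 ± 0.0569 FPKM with CpG-A and 39.9 ± 7.69 with CpG-B, a log2 difference of 5.17 ± 0.24 (adjusted p = 5.33e-08). Ccl4, at 44.7 ± 5.76 and 4.42 ± 0.59 FPKM, was lower by a log2 difference of -3.07 ± 0.21, and Apoe, at 488 ± 22.6 and 43.1 ± 15.9 FPKM, by -3.55 ± 0.30. Glycolysis genes were higher in 14 of 16 cases, G2/M genes in 19 of 20, and feedback inhibitors in 8 of 14 with 1 lower, among them Socs3 (3.95 ± 0.29). Plasma cell genes were higher in 8 and lower in 1 of 16 cases (9 and 2 adjusted over the list alone), with Prdm1 higher by 1.75 ± 0.11. MYC and ribosome biogenesis genes were lower in 14 of 17 cases (16 adjusted over the list alone, 7 with median-of-ratios, 14 with upper-quartile and 16 with TPM scaling), such as Odc1, ornithine decarboxylase (-1.36 ± 0.18), while Myc did not pass (-0.64 ± 0.27, adjusted p = 0.0686).

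The lists were called at adjusted p = 2.01e-15 (glycolysis), 3.24e-12 (G2/M), 2.81e-05 (feedback), 8.48e-06 (plasma cell) and 0.00169 (MYC), and with an estimated correlation at adjusted p = 0.0604, 0.176, 0.127, 0.286 and 0.589. Interferon genes were higher with CpG-B in 10 and lower in 2 of 28 cases (9 and 1 adjusted over the list alone, 16 and 1 with median-of-ratios, 15 and 1 with upper-quartile and 8 and 2 with TPM scaling), with Oas1a higher (1.84 ± 0.39), Ifit3 lower (-1.60 ± 0.33) and neither Irf7 (-0.47 ± 0.28, adjusted p = 0.167) nor Isg15 (0.66 ± 0.40, adjusted p = 0.173) past the test. Also called were interferon-gamma-inducible genes (5 of 10 higher), class switching (6 higher and 2 lower of 11), pro-apoptotic genes (4 of 12 higher, 8 with median-of-ratios, 6 with upper-quartile, and 4 higher and 2 lower with TPM scaling) and G1/S (2 of 22 higher, the cyclins Ccnd2 and Ccnd3). For interferon and these 4 lists adjusted p = 1.88e-05, 0.000633, 0.000781, 0.00092 and 0.00781, and with an estimated correlation adjusted p = 0.507, 0.281, 0.0849, 0.0706 and 0.655. Cytokine genes were higher in 4 and lower in 7 of 13 cases, antigen presentation genes in 2 and 10 of 18 (3 and 11 adjusted over the list alone, 5 and 7 with median-of-ratios and 4 and 9 with upper-quartile scaling), quiescence genes in 0 and 8 of 16 (1 and 9, but 5 and 6 with median-of-ratios and 3 and 7 with upper-quartile scaling), anti-apoptotic genes in 3 and 1 of 9 (3 and 3 with TPM scaling), and Toll-like receptor genes in 3 and 7 of 18 (4 and 4 with median-of-ratios scaling), and none of these was called (adjusted p = 0.791, 0.46, 0.237, 0.0871 and 0.943). Tlr9 was lower with CpG-B (-1.17 ± 0.27, adjusted p = 0.00493). The balance turned with the scaling for 4 lists that were not called. These were NF-kappaB (7 higher and 5 lower, 7 and 6 adjusted over the list alone, 7 and 8 with TPM scaling), activation (6 and 5, 6 and 6 adjusted over the list alone, 6 and 8 with TPM scaling), B cell identity (5 and 7, 9 and 5 with median-of-ratios scaling) and marginal zone (4 and 3, 3 and 4 with TPM scaling), at adjusted p = 0.0814, 0.0756, 0.492 and 0.352.

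Between CpG-B and CpG-A 2082 genes were higher and 4992 lower with CpG-B, a share of 29.4% higher that was 58.6%, 43.1% and 15.1% with median-of-ratios, upper-quartile and TPM scaling. The direction of small differences between these classes thus depended on the scaling, under which the median log2 difference of all genes went from -0.235 to -0.064, -0.167 and -0.407. At least 2-fold, 437 were higher and 543 lower. That split was 413 and 1221 with TPM scaling, 626 and 4364 with a pseudocount of 0.1, and turned to 377 and 245 for known genes only.

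CpG-C differed from CpG-A in much the same lists. Slc16a3 was higher with CpG-C by a log2 difference of 5.26 ± 0.24 (adjusted p = 8.63e-08), Prdm1 by 1.59 ± 0.11 and Il10 by 2.07 ± 0.16, while Ccl22, at 19.1 ± 1.42 FPKM with CpG-A and 0.443 ± 0.604 with CpG-C, was lower (-3.88 ± 0.21). Glycolysis genes were higher in 15 of 16 cases, G2/M genes in 20 of 20, feedback inhibitors in 7 with 2 lower of 14 (8 and 3 adjusted over the list alone) and plasma cell genes in 8 with 2 lower of 16. MYC and ribosome biogenesis genes were lower in 12 of 17 cases (14 adjusted over the list alone), but in 1 with median-of-ratios, 6 with upper-quartile and 14 with TPM scaling. The third CpG-C library stood apart in such genes, with Myc at 68.2 FPKM and Odc1 at 93.6 FPKM, against 33.6 to 34.4 and 54.8 to 55.8 FPKM in the other CpG-C libraries and means of 60 and 127 FPKM with CpG-A. Quiescence genes were lower in 9 of 16 cases, and with median-of-ratios scaling 2 were higher and 5 lower. These lists were called at adjusted p = 4.17e-20, 1.47e-16, 2.05e-06, 1.35e-05, 0.0237 and 0.0499, and with an estimated correlation they had adjusted p = 0.0604, 0.119, 0.11, 0.286, 0.676 and 0.655. Interferon genes were higher in 5 and lower in 2 of 28 cases, but in 4 and 4 with TPM scaling (adjusted p = 0.044, or adjusted p = 0.758 with an estimated correlation), with Irf7 lower (-0.99 ± 0.28, adjusted p = 0.0164) and Isg15 not past the test (0.12 ± 0.40, adjusted p = 0.816).

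Also called in CpG-C against CpG-A were interferon-gamma-inducible genes (4 higher and 1 lower of 10), G1/S (2 higher of 22), class switching (6 higher of 11), anti-apoptotic (4 higher of 9, but 2 higher and 2 lower with TPM scaling), pro-apoptotic genes (5 higher and 1 lower of 12, 6 and 1 adjusted over the list alone, 8 and 0 with median-of-ratios scaling) and NF-kappaB targets (8 higher and 5 lower of 17, 8 and 6 adjusted over the list alone, but 6 and 7 with TPM scaling). For these 6 lists adjusted p = 0.0179, 0.00034, 0.000105, 0.0349, 0.00034 and 0.0248, and with an estimated correlation adjusted p = 0.426, 0.562, 0.0604, 0.255, 0.0604 and 0.281. Antigen presentation genes were lower in 13 and higher in 1 of 18 cases (2 higher adjusted over the list alone, 8 lower and 4 higher with median-of-ratios and 11 and 2 with upper-quartile scaling), led by H2-Oa (-1.40 ± 0.32). Cytokine genes were higher in 4 and lower in 7 of 13 (8 adjusted over the list alone), but neither list was called (adjusted p = 0.11 and 0.768). Not called either were activation (6 higher and 5 lower of 16, adjusted p = 0.0687), marginal zone (3 and 4 of 10, 0.704), B cell identity (4 and 8 of 21, 5 and 8 adjusted over the list alone, 7 and 5 with median-of-ratios scaling, 0.926) and Toll-like receptors (3 and 6 of 18, 3 and 7 adjusted over the list alone, 3 and 1 with median-of-ratios scaling, 0.999). Of all genes 1815 were higher and 4641 lower with CpG-C, and the 28.1% that were higher became 56.3%, 40.4% and 15.3% with median-of-ratios, upper-quartile and TPM scaling. At least 2-fold, 323 were higher and 518 lower. That split was 334 and 1159 with TPM scaling, 514 and 4413 with a pseudocount of 0.1, and turned to 283 and 190 for known genes only. The count of all changed genes, 6456, was 3820 and 3911 without CpG-A library 1 or 2, and 4223 and 4154 without CpG-C library 1 or 2.

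Some genes moved in opposite directions. Against control, 146 genes changed one way with CpG-A and the other way with CpG-B with a called difference between them, and 86 did so with CpG-C. These counts depended on the setting, with 236 and 107 under TPM scaling, 109 and 60 with the filter at 5 FPKM, and 447 and 358 without the third CpG-B and CpG-C libraries. Lck, a Src-family kinase, stood at 79.3 ± 4.87 FPKM in the controls, 107.5 ± 1.55 with CpG-A, 22.9 ± 3.12 with CpG-B and 42.3 ± 3.8 with CpG-C. Lta, lymphotoxin alpha, stood at 7.51 ± 0.846, 10.0 ± 0.849, 1.04 ± 0.426 and 0.88 ± 0.115 FPKM, and Cd69 at 27.3 ± 1.79, 17.9 ± 1.12, 60.6 ± 9.60 and 51.0 ± 3.68 FPKM, in the same order.

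**Figure D4:**
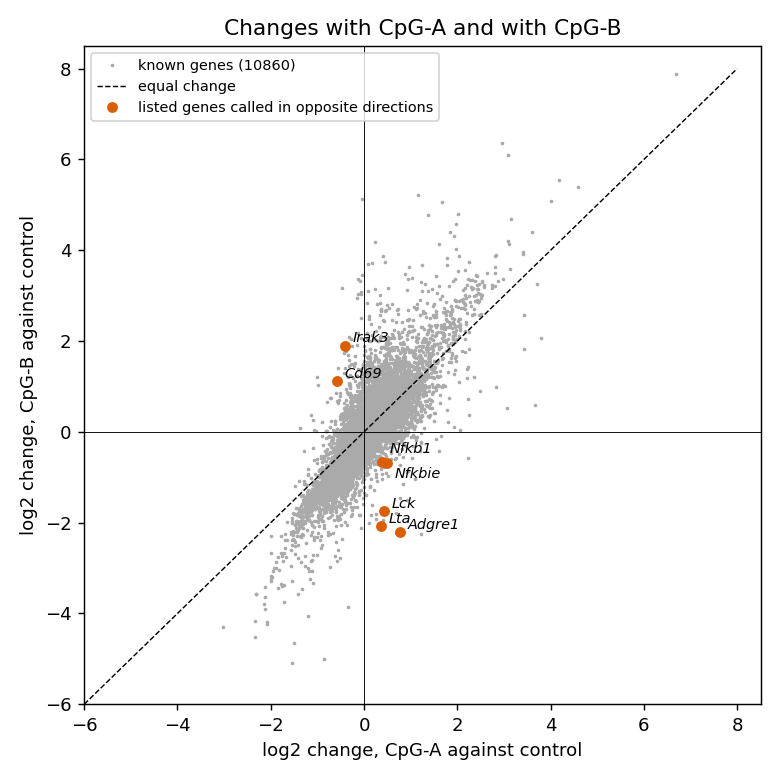
Log2 change against control of 10860 known genes with CpG-A (one axis) and CpG-B (other axis), with the line of equal change and 7 listed genes that changed in opposite directions. Lck lies at 0.44 with CpG-A and -1.75 with CpG-B, and Irak3 at -0.41 and 1.90.

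CpG-C and CpG-B, both fully phosphorothioate classes, gave close expression levels, and the few genes that passed included members of the Egr family, Ccl4, Lck and Ddit3. Egr3, an immediate-early transcription factor (gene 13655, chromosome 14, 70077445 to 70082613), was at 16.8 ± 0.908 FPKM with CpG-B and 37.2 ± 4.05 with CpG-C (log2 1.10 ± 0.08, adjusted p = 0.000319). Egr2 (1.41 ± 0.20) and Egr1 (0.86 ± 0.09) of the same family were higher too, as were Ccl4 (1.63 ± 0.21; gene 20303, chromosome 11, 83662584 to 83664683) and Lck (0.86 ± 0.10; gene 16818, chromosome 4, 129548344 to 129573641). Lower with CpG-C were Cox6a2, a cytochrome c oxidase subunit (-0.97 ± 0.13), Ddit3, the stress-induced transcription factor CHOP (-0.91 ± 0.11), and Irak3, an inhibitor of Toll-like receptor signalling (-0.45 ± 0.08). In all, 18 genes were higher and 11 lower, of 914 at an unadjusted p under 0.05.

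This count of 29 moved with the fit. With limma it was 30 with the replicate number as a block for all 12 libraries, 0 in a fit of only these 6 libraries (973 at an unadjusted p under 0.05), 0 in these 6 with the block (2613), and 139 with the block for the CpG-B and CpG-C libraries only (72 higher and 67 lower), a fit added after the others had been seen. It was 8 without CpG-B library 1, 7 without CpG-B library 2, 1 without CpG-C library 1, 15 without CpG-C library 2, and 87 without the third libraries of both. TPM scaling gave 78.3% higher against 62.1%.

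The difference between CpG-C and CpG-B was bounded for known genes with a mean of at least 10 FPKM in either group, of which 6179 of 6270 (98.5%) had a 95% interval within 2-fold either way. Genes near 0 FPKM cannot be bounded in this way, since log2(FPKM + 1) hides their changes. Pgk1 differed by a log2 of 0.02 (-0.18 to 0.23), Prdm1 by -0.16 (-0.39 to 0.08), Myc by 0.17 (-0.42 to 0.76) and Tlr9 by 0.30 (-0.29 to 0.88). Isg15, at -0.55 (-1.41 to 0.32), was left open beyond 2-fold. Members of the interferon list had a median log2 difference of -0.445, with 0 of 28 past limma's test, and camera called the list at adjusted p = 2.4e-11, or adjusted p = 0.286 with an estimated correlation. For Isg15 and Usp18, a protease that removes ISG15, the gap lay in the first libraries and not in the third. Isg15 stood at 31.5, 31.8 and 52.5 FPKM with CpG-B and 15.9, 18.4 and 55.1 FPKM with CpG-C. Usp18 stood at 18.6, 19.2 and 25.5 FPKM and at 8.40, 7.48 and 26.8 FPKM. Camera also called lower interferon-gamma-inducible, marginal zone and activation lists (adjusted p = 0.000194, 0.0236 and 0.0499) and higher glycolysis, G2/M and MYC lists (3.2e-07, 1.08e-05 and 6.48e-05), each with 0 members past limma's test in the fit without pairs. With an estimated correlation these 6 lists had adjusted p = 0.255, 0.286, 0.281, 0.13, 0.287 and 0.496. With the block for the CpG-B and CpG-C libraries only, 1 MYC member passed as higher, 1 activation member (Il2ra, -0.60 ± 0.06) and 1 antigen presentation member as lower, and 1 marginal zone member each way. Feedback inhibitors then had 1 higher and 2 lower, among them Socs3 (-0.45 ± 0.06). In the fit without pairs the lists with a changed member were cytokines (1 higher), Toll-like receptors and feedback inhibitors (Irak3, lower), T cell markers (Lck, higher) and dendritic cell markers (1 higher, 1 lower). Adjusted over the list alone, members higher and lower numbered 2 and 0 for cytokines, 4 and 0 for NF-kappaB, 2 and 2 for feedback, 1 and 0 for glycolysis and for anti-apoptotic genes, 0 and 1 for activation, plasma cell and quiescence, 0 and 2 for marginal zone, and 1 and 1 for T cell and for monocyte markers.

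The responses to the classes overlapped. Higher with all 3 classes were 2783 genes, 2642 of them known, against 252 for independent lists, and lower 6359, 2109 of them known, against 1775. CpG-A and CpG-B shared 2834 higher and 6369 lower genes (963 and 3463 for independent lists), CpG-A and CpG-C 3061 and 6461 (979 and 3424), and CpG-B and CpG-C 3757 and 7862 (1065 and 4213). Across genes, which are not independent replicates, log2 changes correlated at r = 0.907 for CpG-A and CpG-B, 0.929 for CpG-A and CpG-C and 0.991 for CpG-B and CpG-C, with covariances of 0.844, 0.869 and 1.33. For known genes only, r was 0.823, 0.868 and 0.984, with covariances of 0.468, 0.488 and 0.831, so part of the correlation rested on unnamed loci. Unchanged groups simulated against the same controls gave r = 0.5, 0.497 and 0.5, covariances of 0.0136, 0.0135 and 0.0136 and an overlap of at most 0 genes in 50 simulations. Signs were shared by 86.6%, 88.8% and 95.6% of genes against 66.6% simulated. With 3 controls no split into parts of at least 2 libraries was possible, so part of the excess may come from the shared controls.

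Markers of other cell types were mostly low. Cd3e, a T cell receptor chain, stood at 1.37 ± 0.295 FPKM in the controls, C1qa, a macrophage complement gene, at 2.08 ± 0.681, and Hba-a1, an erythroid globin, at 1.39 ± 0.11. These levels lay near the median of the unnamed loci in the controls (1.73 FPKM) and above the mean of the receptor genes there (0.216 FPKM). Whether the controls held a small share of other cells was not tested. T cell markers rose in 2 and fell in 3 of 7 cases with CpG-A, 1 and 4 with CpG-B, and 1 and 5 with CpG-C. Monocyte and macrophage markers rose in 3 and fell in 1 of 5 with CpG-A, 2 and 2 with CpG-B, and 3 and 2 with CpG-C, with rises of Ly6c2, a Ly6 family gene whose reads can be shared (log2 3.60 ± 0.54 with CpG-A). Dendritic cell markers fell in 1 of 6 with CpG-A and rose in 3 and fell in 3 with CpG-B and with CpG-C, where Flt3, a cytokine receptor, was at 6.46 ± 3.25 FPKM against 0.477 ± 0.166 in the controls. Erythroid and platelet markers fell in 3 of 3, 3 of 3 and 2 of 3. Against CpG-A, T cell markers were higher in 2 and lower in 4 of 7 with CpG-B (3 and 4 adjusted over the list alone) and in 1 and 4 with CpG-C, and monocyte markers in 1 and 2 of 5 and in 1 and 1. In the same comparisons dendritic cell markers were higher in 3 and lower in 3 of 6 with each class, and erythroid markers lower in 1 of 3 with each. None of these lists was called in any comparison, and the lowest adjusted p was 0.196. The NK cell list had 1 measured gene, Prf1, higher with CpG-B than with CpG-A (0.48 ± 0.18) and, adjusted over the list alone, also with CpG-C, and the neutrophil list 0.

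Median, mean and test differed in sign for some lists. With CpG-A these were antigen presentation, dendritic cell and Toll-like receptor lists, with CpG-B antigen presentation and Toll-like receptors, and with CpG-C Toll-like receptors. Against CpG-A they were NF-kappaB (CpG-B), Toll-like receptors (CpG-B), erythroid markers (CpG-C), and activation, B cell identity, marginal zone and monocyte markers (both classes). In CpG-C against CpG-B they were cytokines, NF-kappaB, anti-apoptotic and monocyte lists, and camera called none of these lists in those comparisons.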

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

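The tests of opposite changes were chosen after the result was seen. Members of the fixed lists were picked out where CpG-A changed a gene one way against control and CpG-B or CpG-C the other way, with a called difference between the classes by limma. Between CpG-B and CpG-A the log2 difference was -2.45 for Lta (adjusted p = 2.08e-07), -1.19 for Nfkbie (5.8e-07), -1.06 for Nfkb1 (7.11e-07), 1.69 for Cd69 (4.12e-07), 2.30 for Irak3 (4.04e-09), -2.19 for Lck (4.51e-08) and -2.99 for Adgre1 (6.64e-07). Between CpG-C and CpG-A it was -2.55 for Lta (1.84e-07), -0.91 for Nfkbie (6.96e-06), -0.814 for Nfkb1 (8.26e-06), 1.46 for Cd69 (2.22e-06), 1.85 for Irak3 (4.32e-08), -1 for Cd9 (9.15e-05), -0.575 for Plac8 (0.00083), -1.33 for Lck (2.89e-06) and -2.57 for Adgre1 (3.47e-06). Nfkbie and Nfkb1 encode inhibitory and precursor members of the NF-kappaB system, Irak3 a negative regulator of Toll-like receptor signalling, and Adgre1 the macrophage antigen F4/80.

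The pattern of opposite changes covered 146 genes for CpG-A and CpG-B and 86 for CpG-A and CpG-C, against 236 and 107 with TPM scaling and 447 and 358 without the third CpG-B and CpG-C libraries. A response weaker with CpG-A by the same factor in every gene was argued against by simulation. Effects of CpG-A set to 0.638 of the others gave at most 3 such genes in 20 simulations. A weaker response whose factor differs between genes was not simulated. Scaling was excluded only as the source of the opposite signs and of the difference between classes. Of the listed differences, which come from 9 genes, 16 of 16 kept both under median-of-ratios, upper-quartile and TPM scaling. Whether each change against control stayed called was not part of this test. With median-of-ratios scaling, NF-kappaB members called lower with CpG-C went from 4 to 1, so Nfkbie and Nfkb1 did not both stay called. T cells as the source of Lck were excluded too, because the other markers of the 14-gene T cell list, of which B cells also express Cd2, had a median of 0.42% of the Lck level with CpG-A. A biological difference between the ODN classes remains a hypothesis, and how far the differing depth or the low signal of the control libraries enter other genes of this pattern was not tested.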

How the results depend on the processing

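Scaling, the filter at 5 FPKM, known genes only, leaving out the third libraries of CpG-B and CpG-C and the blocks fitted within 6 libraries or for CpG-B and CpG-C only were added after the data were seen. With median-of-ratios scaling the share higher went from 29.4% to 58.6% for CpG-B and from 28.1% to 56.3% for CpG-C against CpG-A. The balance of a list turned with the scaling in 8 cases, each a list in a single comparison, with ties not counted. They came from the Toll-like receptor, NF-kappaB, activation, B cell identity and marginal zone lists. Whether single named genes reversed under these settings was not counted gene by gene. Without a filter on low values the counts were 16891 (CpG-A), 19869 (CpG-B) and 19856 (CpG-C) against control and 19 for CpG-C against CpG-B. The filter at 5 FPKM gave 5191, 6578 and 6590 against control and 3977 for CpG-C against CpG-A, and known genes only gave 5873, 7609 and 7626, since fewer genes were tested. For CpG-C against CpG-B (29) the count was 0 in the 6 libraries alone (smallest adjusted p = 0.0754), 0 with the replicate block within them (0.0676), 139 with the replicate block for CpG-B and CpG-C only, which held all 29, and 87 without the third libraries of both, and the cause was not tested. With the replicate block in all 12 libraries the counts were 10645, 12508, 12483, 7668 (CpG-B against CpG-A), 7026 (CpG-C against CpG-A) and 30. Outside CpG-B and CpG-C the pairing check did not pair the libraries, and within these classes it settled no more than that the third libraries deviate together. Not every library correlated best with its own number, as CpG-B library 2 did with CpG-C library 1.

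Gene list calls went from 74 of 138 to 0 with an estimated correlation, 76 with the replicate block, 79 without a filter, 71 with median-of-ratios scaling and 53 at 5 FPKM. Genes changed by all 3 classes numbered 9142, and 15355 without a filter, 4701 for known genes only, 9349 with the replicate block and 9281 with upper-quartile scaling. Leaving out 1 library gave 9449 to 9842 (CpG-A), 11662 to 11991 (CpG-B) and 11680 to 11967 (CpG-C) against control, 4732 to 6327 for CpG-B and 3820 to 5584 for CpG-C against CpG-A, and 1 to 28 for CpG-C against CpG-B. Counts moved by over 1.5 times in CpG-C against CpG-A without CpG-A library 1 (3820) or 2 (3911) or CpG-C library 1 (4223) or 2 (4154), and in CpG-C against CpG-B without CpG-B library 1 (8) or 2 (7) or CpG-C library 1 (1) or 2 (15). Among named genes of CpG-C against CpG-B, Egr3 still passed limma's test without CpG-C library 1 (adjusted p = 0.00177), and no other gene did. Ccl4 did not pass without that library (adjusted p = 0.0548) or without CpG-B library 1 (0.0588) or 2 (0.0739). In the 6-library fits of this comparison, with or without the block, no gene passed. How many named genes kept their call in the other comparisons was not counted. A pseudocount of 0.1 kept each count of changed genes within 1.5 times. Counts at least 2-fold moved further against CpG-A, from 980 to 4990 (CpG-B) and from 841 to 4927 (CpG-C) with that pseudocount and to 1634 and 1493 with TPM scaling. Against control they went from 4324, 6580 and 6541 (CpG-A, CpG-B, CpG-C) to 1135, 2111 and 2075 with the filter at 5 FPKM and to 1057, 2263 and 2221 for known genes only. The other tool and its size factors, upper-quartile scaling of counts and a filter on CPM were not run, since the table holds FPKM. At 14.3 to 17.2 M fragments the controls measured low genes least precisely.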

Other observations

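Of the tests here, that of a swap of the third CpG-B and CpG-C libraries was set before its result was seen, and the others, with the genes named in the next paragraph, were chosen after the result was seen.

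Within the CpG-B and CpG-C groups the third libraries had higher Mcm5 and Asns and lower Eno2 and Bnip3. Mcm5, a subunit of the replicative helicase, stood at 128 and 122 FPKM in the third CpG-B and CpG-C libraries, against 62.2 and 64.4 FPKM in the other CpG-B and 70 and 69.6 FPKM in the other CpG-C libraries. Eno2, a neuronal enolase that hypoxia induces, stood at 7.08 and 5.86 FPKM against 23.6, 19.9, 30.5 and 34.2 FPKM. Bnip3, a hypoxia-induced mitophagy gene, stood at 25.8 and 23.4 FPKM against 49.1, 48.5, 74.4 and 73.3 FPKM. Asns, the amino-acid-response gene of asparagine synthesis, stood at 110.6 and 53.8 FPKM against 38.2, 40.3, 28.5 and 30.6 FPKM.

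Splits of the 6 libraries of 2 groups into 3 and 3 number 10, too few for a share under 0.05, and 1 split, the real one, gave as many genes in each comparison. The real count and the highest of the other splits were 10426 and 74 for CpG-A, 12294 and 0 for CpG-B and 12268 and 0 for CpG-C against control. They were 7074 and 0 for CpG-B against CpG-A, 6456 and 2 for CpG-C against CpG-A, and 29 and 0 for CpG-C against CpG-B. The other splits mix libraries of both groups, so a true difference widens the spread within their parts. Their low counts therefore do not show what unchanged groups would give.

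Low signal at unnamed loci and silent receptor genes was higher in the control libraries. A larger number of mapped fragments in the controls was excluded, as the deepest control held an estimated 17.15 M and the shallowest treated library 21.23. These estimates cover mapped fragments only, so they cannot tell how many reads were sequenced. The 50 most abundant genes held 20.03% to 20.51% of all FPKM in the control libraries and 25.53% to 26.61% with CpG-B. This larger part as the source of the falls was argued against by known genes, whose median log2 change with CpG-B was 0.0024. A background shared by silent parts of the genome remains a candidate explanation, since unnamed loci and receptor genes fell in the same order. The median over unnamed loci of the ratio of group means to control, with 0.01 FPKM added to each mean, was 19.7%, 4.24% and 3.38% with CpG-A, CpG-B and CpG-C. The ratio of the mean level of receptor genes was 23.2%, 6.24% and 5.36%, log2 falls that differed by at most -0.666. Whether it is genomic DNA or RNA, and whether more RNA per activated cell diluted it, stays open.

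The third CpG-B and CpG-C libraries deviated from their groups together, at r = 0.745 across genes. A bias by transcript length or GC content was excluded as the whole source. For known genes r was 0.792 before and 0.779 after trends with length, GC content and level were removed. GC content was known for 96.8% of known genes. A trend with length was present, with rank correlations of -0.42 and -0.28 in the third CpG-B and CpG-C libraries. The other libraries of these classes had 0.23 to 0.42. Length and GC content together accounted for 16.4% and 7.3% of the deviations of the third libraries. A batch of the third libraries of all groups was argued against by correlations of at most 0.015 with the third control and CpG-A libraries. These ran over all genes tested, unnamed loci included, and known genes alone were not checked. The third control and CpG-A libraries correlated at 0.518 with each other. A swap of these libraries was excluded, since 87.4% of the 87 genes called between the other libraries had the same sign in the third. A day or batch that only these libraries share stays open, and no biological explanation was tested.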
